A study of Danio rerio with 8 samples.

How the data were processed

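RNA from sorted zebrafish cells was measured on 8 Agilent zebrafish (V3) arrays with 2 colours each. Per the labels, Tg(kdrl:GFP) fish, whose vessels carry a fluorescent protein, were exposed to the dye DAPI, dissociated and sorted by fluorescence. Total RNA was extracted with Trizol, and 50 ng was amplified and labelled with the low-input Agilent kit. The arrays fall into 4 comparisons with 2 biological replicates each. Endothelial cells (ECs) of the adult brain at 6 months were set against ECs of the adult liver. At 3 days after fertilization, DAPI-positive ECs were set against DAPI-negative ECs, total ECs against non-ECs, and ECs of gpr124 mutants against wild-type ECs. In each comparison the cells named before "against" were labelled with Cy3 and their partner with Cy5, per the labels, with no dye swap, so a gene-specific dye effect cannot be separated from any single comparison. The groups were taken from the titles and tissue labels. The free-text description of the total EC arrays names ECs in both channels, unlike their tissue labels and title, and the tissue labels were followed.

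The deposited spot intensities (mean signal and median local background per channel) came from Agilent Feature Extraction, version 10.7.3.1 for the adult and DAPI arrays and version 10.10.1.1 for the others, per the file headers. The processed intensities in the same files had been background-subtracted, detrended and dye-normalized by the software, per the file headers. The deposited log10 ratios give processed red over green, per the file headers. The deposited series matrix holds log2 ratios with Cy3 over Cy5. Its columns had a slope of -1 and correlations of -0.98 to -1 with the log10 ratios of the same arrays once these were put on the log2 scale. Their medians were -0.007 and -0.001 for the adult arrays, 0.057 and -0.056 for DAPI, 0.24 and 0.269 for total ECs, and -0.048 and -0.117 for gpr124. Its scale and direction were read from this match, and no further centring step is given in the sources used here. The files also carry flags for saturation, outliers and signal above background, per the file headers. The adult and DAPI arrays share 1 slide and the total EC and gpr124 arrays another, so each comparison lies within 1 slide.

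Arrays were processed in R 4.3.3 with limma 3.58.1. The background was corrected with normexp (offset 50), the log2 ratios were normalized by loess within each array with control spots at weight 0, outlier spots were left out, and repeated spots of a probe were averaged. Of 43603 distinct probes, 28214 (64.7%) were named through an accession in the reference tables, 4086 (9.4%) through a current symbol and 836 (1.9%) through a synonym. The other 10467 (24.0%) kept the file's own name. Of the probes, 37742 passed a filter that asked for signal well above background in at least 1 channel on both arrays of at least 1 comparison. Each gene was represented by its brightest probe over the 8 arrays, which gave 22280 genes, 14445 of them with a gene symbol. Among 9476 genes with several probes, probes of called genes lay on opposite sides of 0 by over 0.5 on the log2 scale for 107 genes in the adult comparison, 48 in DAPI, 45 in total ECs and 0 in gpr124. Of the genes that were always to be named, fli1a, pecam1, reck and stab2 were not among the genes tested.

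All 8 arrays entered a single limma model (lmFit and eBayes) with a coefficient per comparison, which left 4 residual degrees of freedom and shared the estimate of spread. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. In all, 33 gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Values are log2 ratios as mean ± SD over n = 2 arrays. Where a gene was not well above background on either array of a group in that group's channel, the difference is given as at least N-fold: the bright group's mean against, per array, the higher of the lowest signal among probes above background and the probe's own, after normalization per channel. Such bounds are open to dye bias. Overlaps of calls were tested with Fisher's exact test, two-sided, against the product of both counts divided by the genes tested, with adjustment over 24 pairs. The groups, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The rule takes, per comparison, the 10 highest and 10 lowest called genes with a symbol, signal above background and the same sign on both arrays. It adds up to 4 members of each called list, a fixed set of vascular and other marker genes, and genes higher in adult brain and DAPI-positive ECs and lower in gpr124 mutants, of which there were 0 by limma (11 at an unadjusted p under 0.05).

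The model was tested on simulated data in which 50 genes per fold size among 22280 were changed. At 2-fold it recovered 30% of the changed genes in the adult design, 40% in DAPI, 34% in total ECs and 36% in gpr124. At 8-fold it recovered 84%, 84%, 84% and 72%, with 0 genes called in the wrong direction and 4 to 9 unchanged genes called per comparison. Errors were simulated independently, with the same spread per gene on all 8 arrays. The rates thus differed between comparisons only by the draw. They do not cover a larger spread on the adult arrays or a deviation shared between comparisons. Alternatives changed the background correction, the normalization, the filter, the treatment of several probes, the estimate of spread, the arrays in the fit, a block for replicate number, the threshold and the arrays left out. The 6 larval arrays alone, a filter on the same channel in both adult arrays and a crossed block were added after the data were seen. The number of arrays limits the precision. The labels call the replicates biological, but nothing says whether they came from separate clutches or sorts, so the p-values measure only the spread between these samples.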

Results

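The data were log2 ratios of gene expression between cell populations hybridized together, on 2 arrays for each of 4 comparisons. The larval arrays were bright: 58.8 to 87.6% of probes per channel lay well above background. The adult arrays were dim, with 19.2 and 25.7% in Cy3 and 27.9 and 35% in Cy5. Their median Cy3 signals were 37.2 and 39.7, against 108 to 259 on the larval arrays. On the adult arrays 2 of 10 kinds of spike-in control were above background in each channel, against 10 of 10 on every larval array. No spot was saturated (0 spots). Across genes, which are not independent replicates, the ratios of both replicates correlated at 0.209 in the adult comparison, 0.880 in DAPI, 0.950 in total ECs and 0.418 in gpr124, and 53.6%, 81.7%, 87% and 66.3% of genes had the same sign on both arrays. Normalization within arrays set the median ratio of all genes near 0, at -0.003 for adult, 0.05 for DAPI, -0.07 for total ECs and 0.02 for gpr124. Without it the medians were -0.20, -0.58, -0.47 and -0.46. The loess step follows intensity, so each change below is relative to genes of similar brightness on the same array.

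The comparison of total larval ECs with non-ECs asked which transcripts mark the larval endothelium, and it gave the clearest separation. The highest gene was plvapb, a component of the diaphragms of endothelial pores and caveolae, at 7.86 ± 0.20 (adjusted p = 6.68e-05). It was followed by fli1rs at 7.50 ± 0.09, clec14a, an endothelial lectin, at 7.37 ± 0.16, and cdh5, the endothelial cadherin, at 7.27 ± 0.14. The reporter's own gene kdrl, a VEGF receptor, rose by 6.21 ± 0.05 (adjusted p = 0.000777). The other genes among the 10 highest were yrk (6.30), adgrl4 (6.21), the scavenger receptor mrc1a (6.20), the chemokine receptor cxcr4a (6.08) and the VEGF receptor flt1 (5.92). The lowest included genes known from skin, fin fold, gut, blood, glia and photoreceptors. The fin fold gene and2 lay at -6.74 ± 3.26, the keratin cyt1 at -6.33 ± 1.26, the epithelial adhesion gene epcam at -6.04 ± 0.56 and the cartilage and bone collagen col10a1a at -6.02 ± 1.16. The embryonic globin hbbe1.1 lay at -5.99, the glial glutamate transporter slc1a2b at -5.97 ± 2.36, cldn15la at -5.95, fabp7a, a radial glia marker, at -5.89, rhodopsin (rho) at -5.86 and tm4sf4 at -5.75.

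Pan-endothelial, arterial, venous and angiogenesis lists rose in total ECs. Of 44 pan-endothelial markers, 39 rose and 2 fell (39 rose and 3 fell when adjusted over the list alone), with a median of 3.65. The list test gave an adjusted p of 2.07e-19, and this was the only list of any comparison that stayed past the threshold otherwise (adjusted p = 0.0459 with an estimated correlation). Examples were pecam1a at 5.58 ± 0.11 and the angiopoietin receptor relative tie1 at 5.33 ± 0.05. Of 25 arterial and Notch genes, 13 rose and 3 fell (16 and 3 adjusted over the list alone; adjusted p = 5.22e-06, and adjusted p = 0.136 with an estimated correlation). The Notch ligand dll4 rose by 4.32, nrp1b by 2.52, aqp8a.1 by 3.08 and efnb2b by 1.94. Of 22 venous, lymphatic and scavenger genes, 13 rose and 2 fell (13 and 2 adjusted over the list alone; adjusted p = 7.65e-07, and adjusted p = 0.211 with an estimated correlation). They included stab1 at 5.01, gpr182 at 4.80 and the lymphatic receptor flt4 at 3.30. Of 55 angiogenesis signalling genes, 30 rose and 6 fell (30 and 7 adjusted over the list alone; adjusted p = 1.28e-08, and adjusted p = 0.064 with an estimated correlation), with pdgfba, a pericyte-recruiting growth factor, at 2.16. Genes of fenestrated and permeable vessels had no call (7 higher and 6 lower of 17, the same adjusted over the list alone; median 0.97, adjusted p = 0.259), nor did the blood-brain barrier list described further on.

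Neutrophil, lymphocyte, cell cycle, immediate early and interferon lists rose as well. Of 14 neutrophil markers, 8 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.0137, and adjusted p = 0.271 with an estimated correlation). Among them cebp1 stood at 1.67, npsn at 1.83, lect2l at 0.89 and mmp25b at least 1.91-fold higher. Of 12 lymphocyte markers, 5 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.00352, and adjusted p = 0.294 with an estimated correlation). The chemokine receptor ccr9a rose by 3.93, ikzf1 by 1.91, il2rga by 1.78 and zap70 by 1.25. Of 75 cell cycle genes, 22 rose and 1 fell (20 and 1 adjusted over the list alone; adjusted p = 7.65e-07, and adjusted p = 0.417 with an estimated correlation), by small amounts such as 0.64 for top2a. Of 43 immediate early genes, 12 rose and 4 fell (11 and 4 adjusted over the list alone; adjusted p = 0.00408, and adjusted p = 0.211 with an estimated correlation), led by the flow-responsive factor klf2a at 2.65. Of 38 interferon and inflammation genes, 9 rose and 5 fell (9 and 5 adjusted over the list alone; adjusted p = 0.0377, and adjusted p = 0.211 with an estimated correlation). Among them were b2m at 3.47 and isg15 at 2.72. Without replicate 2 that adjusted p was 0.0654, and with the software's processed signals 0.102.

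Markers of several other tissues fell in total ECs. Of 56 hepatocyte markers, 42 fell and 1 rose (43 and 1 adjusted over the list alone; adjusted p = 1.36e-10, and adjusted p = 0.211 with an estimated correlation). The liver fatty acid binding protein fabp10a stood at -4.94 and apoa2 at -4.26. Of 47 neuron markers, 33 fell and 0 rose (33 adjusted over the list alone; adjusted p = 5.74e-08, and adjusted p = 0.211 with an estimated correlation). The neuronal genes elavl3 and gap43 stood at -5.32 and -3.41. Of 35 astroglia and oligodendrocyte markers, 27 fell and 1 rose (28 and 1 adjusted over the list alone; adjusted p = 1.08e-06, and adjusted p = 0.234 with an estimated correlation), with gfap at -3.43 and gpm6ba at -2.79. Of 41 epidermis and epithelial markers, 35 fell and 4 rose (35 and 4 adjusted over the list alone; adjusted p = 5.74e-08, and adjusted p = 0.294 with an estimated correlation), with the lowest median of the lists, -3.93, and evpla at -4.63. Of 48 eye and lens markers, 39 fell and 0 rose (41 adjusted over the list alone; adjusted p = 1.1e-09, and adjusted p = 0.211 with an estimated correlation).

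Other lists fell as well. Of 44 skeletal muscle markers, 21 fell and 0 rose (23 adjusted over the list alone; adjusted p = 2.49e-05, and adjusted p = 0.556 with an estimated correlation), with tnni2a.1 at -2.92. This list's median was -1.49 on replicate 1 and -4.41 on replicate 2. Of 29 erythroid markers, 18 fell and 3 rose (19 and 3 adjusted over the list alone; adjusted p = 0.00112, and adjusted p = 0.136 with an estimated correlation), with hbaa2 at -3.73. Of 29 cartilage and fibroblast markers, 19 fell and 2 rose (19 and 2 adjusted over the list alone; adjusted p = 0.00123, and adjusted p = 0.417 with an estimated correlation), with postnb at -3.00. Of 36 exocrine pancreas and intestine markers, 19 fell and 0 rose (21 adjusted over the list alone; adjusted p = 0.000151, and adjusted p = 0.499 with an estimated correlation), with the villus gene vil1 at -4.65. Of 59 claudins and tight junction genes, 34 fell and 10 rose (36 and 11 adjusted over the list alone; adjusted p = 0.00352, and adjusted p = 0.403 with an estimated correlation). The epithelial members cldn8.2 (-4.82) and oclna (-3.24) fell, and the endothelial claudins cldn5b (4.40 ± 0.09) and cldn5a (2.41 ± 0.08) rose. Of 96 oxidative phosphorylation genes, 20 fell and 0 rose (14 adjusted over the list alone; adjusted p = 0.0137, and adjusted p = 0.569 with an estimated correlation), with ndufa4b at -2.52. Without replicate 1 its adjusted p was 0.0688.

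In all, 3306 genes were higher and 5863 lower in total ECs, 1100 and 3195 of them by at least 2-fold. With replicate 1 left out the model called 5315 genes, and with replicate 2 left out 4906, of which 5293 and 4885 were among the 9169. The split was 2381 higher and 5822 lower after median centring, and 1082 and 8696 with no normalization. Of 68 named genes that passed here and had several probes, 7 had another probe within 0.5 of 0 on the log2 scale. The blood-brain barrier list had no call here, with 13 members higher, 17 lower and 25 not passing of 55 (adjusted p = 0.497). Its member abcb4, the fish P-glycoprotein, was higher by 2.43 ± 0.14, whereas slc2a1a, the glucose transporter GLUT1, stood at 1.45 ± 0.17 (adjusted p = 0.0669) and the Wnt effector lef1 at 0.15 ± 0.01 (adjusted p = 0.744). The gene gpr124 (adgra2), a Wnt co-receptor component of brain vessels, rose by 0.81 ± 0.04 (adjusted p = 0.0199). The 2 probes of plvapa disagreed, at -0.43 for the brighter and 3.67 for the other, so its direction is not settled; their mean was 1.62.

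**Figure D1:**
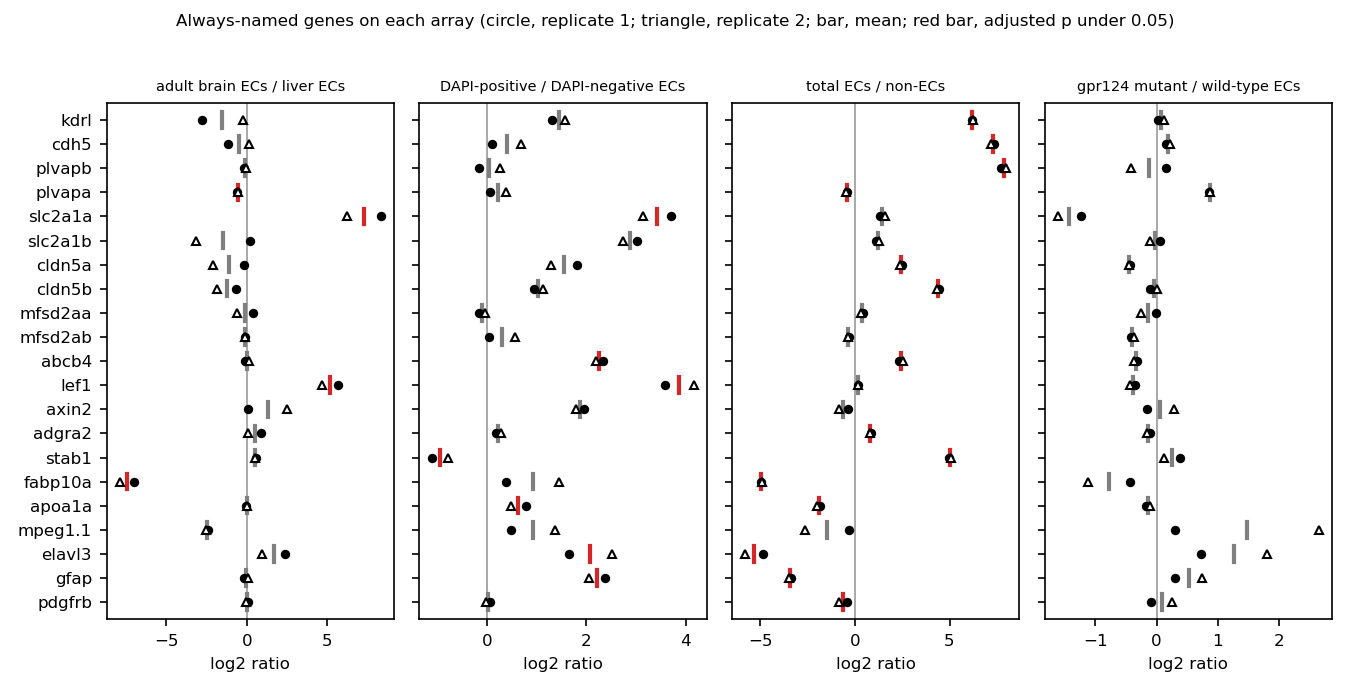
Log2 ratios (x axis) of the 21 measured genes of the fixed marker set (y axis) in the 4 comparisons; circles are replicate 1, triangles replicate 2, bars the mean, and red bars genes with an adjusted p under 0.05. The endothelial genes kdrl, cdh5 and plvapb lie at 6.21, 7.27 and 7.86 in total ECs, and lef1 and slc2a1a lie to the right in both the adult and the DAPI comparison.

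The comparison of DAPI-positive with DAPI-negative larval ECs asked, by the design text, what sets the DAPI-positive vascular cells apart from the peripheral vessels. Genes known from the blood-brain barrier were among the highest. The highest was slco1c1, a thyroid hormone transporter of brain capillaries, at 5.34 ± 0.17 (adjusted p = 0.00769), and slc7a5, a large neutral amino acid transporter, rose by 4.05 ± 0.03 (adjusted p = 0.00144). The Wnt effector lef1 rose by 3.88 ± 0.40 (adjusted p = 0.00277), with probe means of 3.88, 2.30 and 1.37, and slc2a1a was at least 8.56-fold higher (adjusted p = 0.0115). The other genes among the 10 highest were epd (4.89), encoding ependymin, a protein of the brain meninges and fluid, tnfrsf9a (4.43), the neural transcription factor zic2a (3.78), the chemokine cxcl12b (3.61), gpd1b (3.45) and tm6sf2b (3.35). The 10 lowest included myb, a regulator of blood stem cells, at -3.31 ± 0.62, runx3 at -2.97 ± 0.36, the leukocyte kinase subunit pik3cd at -2.88 and ccr9a at -2.86 ± 0.60. The others were drll.2 (-3.36), blf (-3.31), agap2 (-3.08), sla2b (-3.06), grap2a (-2.80) and psme1 (-2.78).

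Of 55 blood-brain barrier genes, 21 rose, 5 fell and 29 did not pass (28 rose and 5 fell when adjusted over the list alone), with a median of 0.66 (adjusted p = 0.000112, and adjusted p = 0.271 with an estimated correlation). Besides those named, abcb4 rose by 2.27 ± 0.10 and zic2b by 2.50 ± 0.54. The tight junction genes cldn5a at 1.55 ± 0.37 (adjusted p = 0.0675) and cldn5b at 1.04 ± 0.12 (adjusted p = 0.0551) did not pass, nor did slc2a1b at 2.88 ± 0.20 (adjusted p = 0.0532). Of 33 Wnt genes, 8 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 0.012, and adjusted p = 0.271 with an estimated correlation), with fzd10 at 1.86 and tcf7l1a at 1.21, whereas axin2 at 1.88 ± 0.13 did not pass (adjusted p = 0.0776). Of 25 arterial and Notch genes, 8 rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 0.00962, and adjusted p = 0.271 with an estimated correlation), with nrp1b at 1.28 and sox17 at 0.85. Of 55 angiogenesis signalling genes, 16 rose and 5 fell (17 and 5 adjusted over the list alone; adjusted p = 0.0189, and adjusted p = 0.271 with an estimated correlation), with pdgfba at 0.89 and vegfc at 1.28. After median centring the arterial list had an adjusted p of 0.139 and the angiogenesis list 0.587, and with the software's processed signals 0.0584 and 0.0788. Of 17 genes of fenestrated and permeable vessels, 5 rose and 0 fell (5 adjusted over the list alone; adjusted p = 0.00623, adjusted p = 0.271 with an estimated correlation and 0.199 after median centring). The members that rose there included the lipid-handling genes fabp4b (3.33), fabp4a (2.98) and lpla (1.49), while plvapb stood at 0.05 ± 0.29 (adjusted p = 0.916). Of 22 venous, lymphatic and scavenger genes, 7 fell and 1 rose (9 and 2 adjusted over the list alone; adjusted p = 0.00116, and adjusted p = 0.313 with an estimated correlation). They included dab2 at -2.69, lyve1b, a lymphatic and venous hyaluronan receptor, at -2.63, mrc1a at -1.58 and flt4 at -1.16. Pan-endothelial markers had no call as a list (8 higher and 3 lower of 44, median 0.26, adjusted p = 0.0921), and kdrl at 1.45 ± 0.18 and cdh5 at 0.40 ± 0.40 did not pass. These tests share their spread with the adult arrays, which varied more (array weights of 0.166 against 1.604 for DAPI). A gene that did not pass is thus not shown to be unchanged. The 6 larval arrays alone, chosen after the data were seen, gained 23 calls of named genes over the larval comparisons and lost 0.

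Markers of other cells moved in the same comparison, beside the barrier genes. Of 47 neuron markers, 11 rose and 0 fell (14 adjusted over the list alone; median 0.66, adjusted p = 6.05e-05, and adjusted p = 0.313 with an estimated correlation). Here elavl3 stood at 2.08 ± 0.61 and gap43 at 1.37, with the other probes of gap43 at 0.01 and -0.02. Of 35 glia markers, 7 rose and 0 fell (12 adjusted over the list alone; median 0.82, adjusted p = 0.000152, and adjusted p = 0.313 with an estimated correlation). The glial filament gene gfap stood at 2.22 ± 0.24, with its other probes at 0.53 and 0.39, and gpm6aa at 1.91. Of 41 epidermis and epithelial markers, 11 rose and 0 fell (23 adjusted over the list alone; median 1.12, adjusted p = 6.68e-07, and adjusted p = 0.313 with an estimated correlation), with anxa1c at 2.68 and agr1 at 2.08. Of 48 eye and lens markers, 11 rose and 0 fell (13 adjusted over the list alone; median 0.81, adjusted p = 0.000693, and adjusted p = 0.381 with an estimated correlation), with sagb at 2.05. Of 44 skeletal muscle markers, 2 rose and 0 fell (0 and 0 adjusted over the list alone; median 1.21, adjusted p = 0.00586, and adjusted p = 0.687 with an estimated correlation), with actc1a at 2.03. Of 56 hepatocyte markers, 4 rose and 0 fell (3 adjusted over the list alone; median 0.24, adjusted p = 0.0351, and adjusted p = 0.452 with an estimated correlation), with apoa4b.1 at 2.16. The list's adjusted p was 0.269 without replicate 2. Of 59 claudins and tight junction genes, 14 rose and 3 fell (19 and 3 adjusted over the list alone; adjusted p = 0.000661, and adjusted p = 0.313 with an estimated correlation). The members that rose most included cldn7a (2.32) and cldn8.2 (1.68), which are epithelial claudins, and cldnf at least 2.36-fold. Cartilage and fibroblast markers had no call (2 higher and 6 lower of 29, median -0.06, adjusted p = 0.104).

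Neutrophil, lymphocyte, thrombocyte, cell cycle, ribosomal and oxidative phosphorylation lists fell in DAPI-positive ECs. Erythroid markers (6 higher and 1 lower of 29, the same adjusted over the list alone; median 0.22, adjusted p = 0.157) and macrophage and microglia markers (4 higher and 3 lower of 35, also when adjusted over the list alone; median 0.25, adjusted p = 0.725) had no call. Of 14 neutrophil markers, 4 fell and 0 rose (8 and 1 adjusted over the list alone; adjusted p = 0.00513, and adjusted p = 0.271 with an estimated correlation), with cebp1 at -2.14 and npsn at -1.20. Of 12 lymphocyte markers, 6 fell and 1 rose (6 and 1 adjusted over the list alone; adjusted p = 0.00445, and adjusted p = 0.313 with an estimated correlation). The lymphocyte genes il2rga, zap70 and lck were at least 2.99-fold, 2.46-fold and 2.17-fold lower. Of 13 thrombocyte markers, 5 fell and 1 rose (6 and 2 adjusted over the list alone; adjusted p = 0.0159, and adjusted p = 0.271 with an estimated correlation). The members fermt3b, gp1bb and mpl stood at -2.17, -2.02 and -2.02. Without replicate 2 the thrombocyte list had an adjusted p of 0.0643. Of 75 cell cycle genes, 39 fell and 0 rose (45 and 1 adjusted over the list alone; median -0.65, adjusted p = 5.35e-18, and adjusted p = 0.298 with an estimated correlation). The condensin subunit ncapd2 stood at -1.46 and rpa2 at -1.43. Of 85 ribosomal protein genes, 32 fell and 1 rose (39 and 1 adjusted over the list alone; median -0.79, adjusted p = 1.91e-18, and adjusted p = 0.271 with an estimated correlation), with rpl26 at -1.27 and rps4x at -0.96. Of 96 oxidative phosphorylation genes, 8 fell and 2 rose (4 and 1 adjusted over the list alone; median -0.15, adjusted p = 0.00205, and adjusted p = 0.452 with an estimated correlation), with ndufaf1 at -1.03. That p was 0.0939 without replicate 2. Of 43 immediate early genes, 10 rose and 1 fell (17 and 2 adjusted over the list alone; median 0.54, adjusted p = 0.00107, and adjusted p = 0.271 with an estimated correlation). This list turned downward, without a call, when arrays were only centred on their median, and its adjusted p was 0.227 when all probes of a gene were averaged.

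In all, 2471 genes were higher and 1860 lower in DAPI-positive ECs, 862 and 509 of them by at least 2-fold, and 148 of the called genes were dim in both channels. The split depended on scaling, with 1632 higher and 2633 lower after median centring and 310 higher and 9874 lower with no normalization. With replicate 1 left out 1160 genes passed and with replicate 2 left out 639, of which 1058 and 619 were among the 4331, and 43 and 48 of the 95 named genes no longer passed, slco1c1, slc2a1a and elavl3 among them. Of 63 named genes that passed and had several probes, 22 had another probe within 0.5 of 0 on the log2 scale. With the dim adult arrays out of the model, 8872 genes passed.

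**Figure D2:**
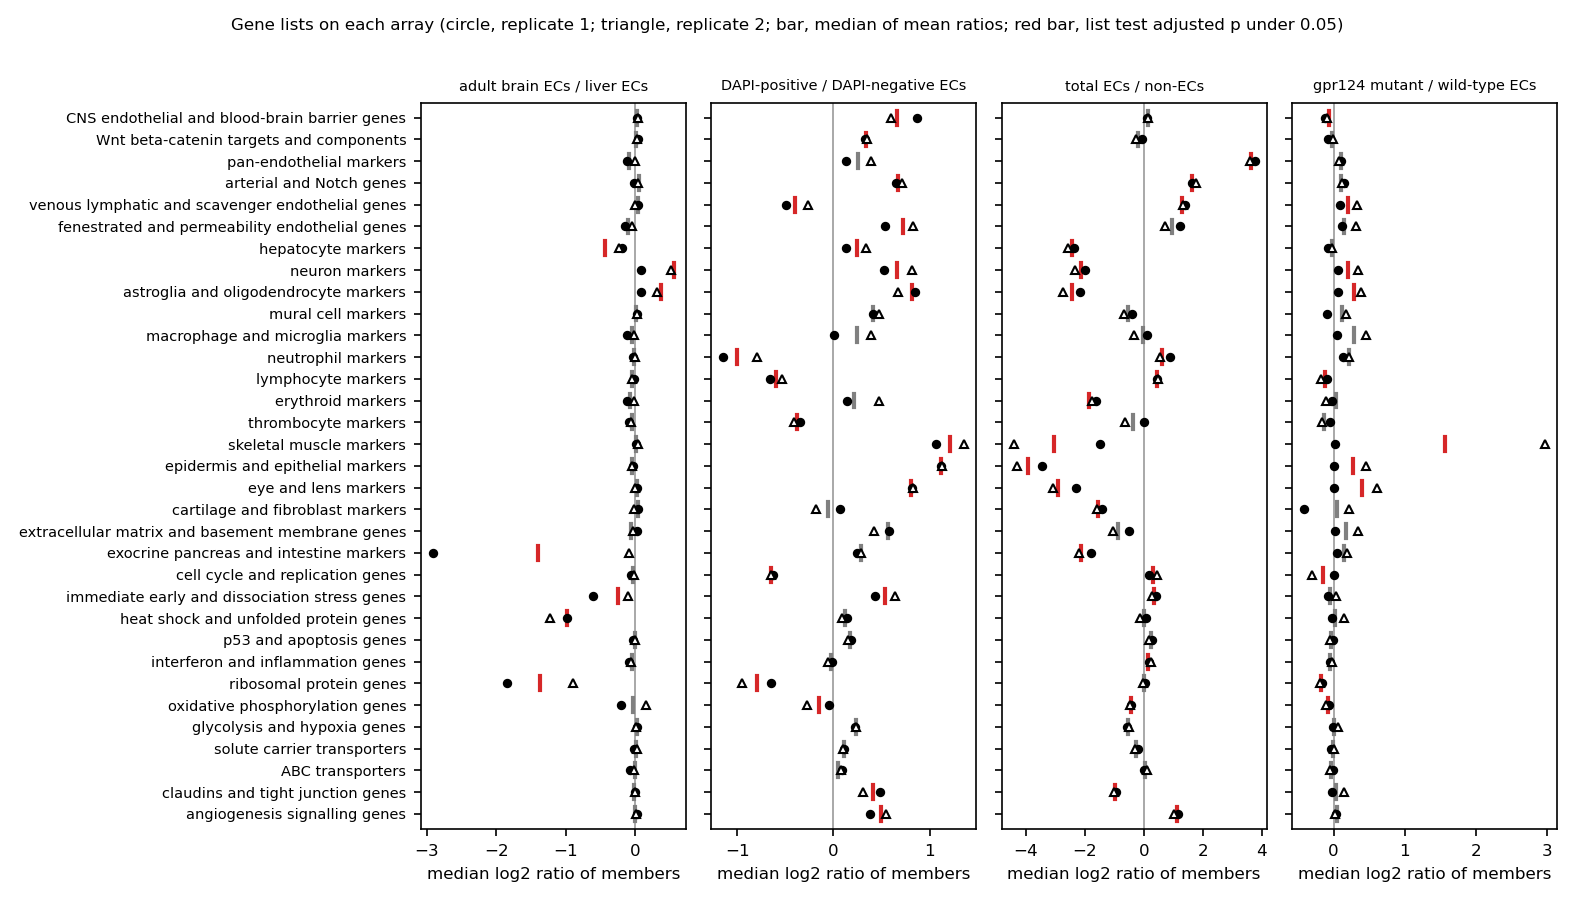
Median log2 ratio of the members (x axis) of the 33 gene lists (y axis) in the 4 comparisons; circles are replicate 1, triangles replicate 2, bars the median of mean ratios, and red bars lists with an adjusted p under 0.05 at the preset correlation. Pan-endothelial markers lie at 3.65 in total ECs, and skeletal muscle markers in gpr124 mutants lie at 0.02 on replicate 1 and 2.97 on replicate 2.

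The adult comparison asked what distinguishes brain ECs from liver ECs. Genes known from brain cells were among the highest and genes known from the liver among the lowest. The highest were ppp6r2b at 7.93 ± 0.09, the neural factor zic5 at 7.78 ± 0.52, the activity-dependent factor npas4a at 7.62 ± 0.83 and mbpa, a myelin protein, at 7.61 ± 0.10. The glucose transporter slc2a1a rose by 7.29 ± 1.49 (adjusted p = 0.00119), and stmn1b (7.33), mtbl (7.32), clic3 (7.25), slc1a2b (7.22 ± 1.04) and the synaptic gene snap25a (7.17) completed the 10 highest. These values are those of each gene's brightest probe: the other probes of zic5 and clic3 gave 0.08 and 0.01, those of stmn1b 0.05 and 0.03, and those of snap25a -0.04 to -0.17. Of 36 named genes that passed in adults and had several probes, 28 had another probe within 0.5 of 0 on the log2 scale. The lowest were vtg5, an egg yolk precursor made by the liver, at -7.91 ± 1.07, emilin1b at -7.70, oit3 at -7.50 and fabp10a at -7.45 ± 0.64 (adjusted p = 0.000358). The yolk genes vtg7 (-7.03), vtg1 (-7.02) and vtg4 (-6.95) followed, with prdx1 (-7.29), cyp24a1 (-6.98) and cntf (-6.41). The Wnt effector lef1 was higher in brain ECs by 5.18 ± 0.73 (adjusted p = 0.000484). The endothelial genes kdrl at -1.53 ± 1.81 (adjusted p = 0.279) and cdh5 at -0.50 ± 0.93 (adjusted p = 0.508) did not pass, and plvapb, abcb4, gfap, apoa1a and pdgfrb were not well above background in either channel.

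Of 56 hepatocyte markers, 15 fell and 0 rose in adult brain ECs (18 adjusted over the list alone; median -0.44, mean -1.92, adjusted p = 2.64e-09, and adjusted p = 0.337 with an estimated correlation), with hpda at -4.61. Of 36 exocrine pancreas and intestine markers, 6 fell and 1 rose (6 and 1 adjusted over the list alone; median -1.40, mean -1.84, adjusted p = 1.15e-05, and adjusted p = 0.602 with an estimated correlation), with the digestive enzyme genes prss59.1 at -6.20 and ctrb.1 at -5.06. That list's median was -2.91 on replicate 1 and -0.09 on replicate 2, and its adjusted p was 0.322 without replicate 1. Of 47 neuron markers, 8 rose and 0 fell (8 adjusted over the list alone; median 0.55, mean 1.31, adjusted p = 0.000115, and adjusted p = 0.56 with an estimated correlation). Here atp1a3b rose by 6.73, nefma by 5.93 and gad1b at least 20.4-fold, while their other probes lay between 0.02 and 0.14, -0.09 and 0.17, and -0.03 and 0.21. The neuron list had medians of 0.09 and 0.51 on replicates 1 and 2, and without replicate 2 an adjusted p of 0.0628. Of 35 glia markers, 7 rose and 0 fell (11 adjusted over the list alone; median 0.37, mean 1.86, adjusted p = 1.15e-05, and adjusted p = 0.538 with an estimated correlation), with sox10 at 6.18 (0.09 by its other probe) and slc1a3a at 5.86 (0.01). Of 85 ribosomal protein genes, 42 fell and 2 rose (55 and 4 adjusted over the list alone; median -1.38, adjusted p = 7.05e-25, and adjusted p = 0.337 with an estimated correlation), with rps4x at -2.41 ± 0.01 and rpl37 at -2.37 ± 0.06. Of 44 heat shock and unfolded protein genes, 18 fell and 0 rose (24 adjusted over the list alone; median -0.98, adjusted p = 1.51e-09, and adjusted p = 0.101 with an estimated correlation). The stress factors ddit3 and xbp1 stood at -4.84 and -3.35. Of 43 immediate early genes, 11 fell and 3 rose (15 and 4 adjusted over the list alone; median -0.25, adjusted p = 0.00219, and adjusted p = 0.337 with an estimated correlation). The factors junba, fosb and egr2a stood at -4.82, -4.76 and -4.12. Its adjusted p was 0.0673 without replicate 1. The blood-brain barrier list had no call in adults (8 higher and 1 lower of 55, median 0.02, mean 0.73, adjusted p = 0.0757).

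In all, 717 genes were higher and 819 lower in adult brain ECs, 610 and 733 of them by at least 2-fold, and 10455 of 22280 genes were dim in both channels on both arrays. The spread estimate was shared with the brighter larval arrays. The adult arrays varied more than these, with estimated array weights of 0.166 against 1.604 to 1.973, a lower weight standing for a larger spread. A model of the 2 adult arrays alone called 0 genes in limma (1154 at an unadjusted p under 0.05), which does not show which arrays supplied the shared spread. With replicate 1 left out 5876 genes passed and with replicate 2 left out 5523, since the remaining adult array was then assumed to vary like the larval ones; 1517 of the 1536 genes were shared with each. The split was 325 higher and 2018 lower after median centring, and 277 and 2421 with no normalization.

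The gpr124 comparison asked how larval ECs change without the receptor that Wnt signalling of brain vessels uses, and few genes passed. Of 18 genes that rose and 2 that fell, 6 had a gene symbol, all higher in mutants. These were agbl4 at 1.58 ± 0.10 (adjusted p = 0.0379), cd4-2.1 at 1.45 ± 0.01 and ttr, the thyroid hormone carrier transthyretin, at 1.31 and 1.28 on its arrays (both adjusted p = 0.0359), with the green opsin opn1mw4 (0.94), nitr1b (0.92) and pimr132 (0.89). The other probes of agbl4, ttr and pimr132 gave 0.53, 0.01 and 0.12. The targeted gene, adgra2, stood at -0.11 and -0.16 (adjusted p = 0.961), but where its probe lies relative to the mutation is not known here, so it checks nothing about the genotype. Several barrier genes had large negative ratios on both arrays that did not pass. The lactate transporter gene slc16a1a stood at -2.76 ± 0.20 (adjusted p = 0.0591), zic2b at -1.38 ± 0.08 (adjusted p = 0.0866), zic2a at -1.43 ± 0.13 (adjusted p = 0.271), slc2a1a at -1.42 ± 0.27 (adjusted p = 0.437) and slco2a1 at -1.18 ± 0.42 (adjusted p = 0.222; its other probes at -0.42 and -0.16). With the 6 larval arrays alone, chosen after the data were seen, these genes passed, with adjusted p of 0.0152, 0.0249, 0.0116, 0.0218 and 0.046, while abcb4 at -0.34 (0.132) did not. Over all alternatives the adjusted p ran from 0.00816 to 0.648 for slc16a1a, and its highest value was 0.961 for zic2b and 1 for the rest. Among alternatives set beforehand, slc16a1a and zic2b passed in limma with the software's processed signals (adjusted p = 0.0271 and 0.0462). They also passed with no background correction (0.0236 and 0.037), but not with an offset of 16 (0.0653 and 0.1075). With the processed signals agbl4, cd4-2.1 and ttr did not pass (0.128, 0.07965 and 0.0811). Which genes passed thus depended on the background treatment. The gene slc2a1a was not well above background in both channels on both gpr124 arrays, and the size of its ratio depended on the background treatment. It stood at -2.01 with an offset of 16 and at -3.80 with the software's processed signals. The permeability gene plvapa stood at 0.87 ± 0.01 (adjusted p = 0.0643) by its brighter probe and at 0.05 by the other, and cldn5a at -0.44 and lef1 at -0.39 ± 0.06 did not pass.

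Of 55 blood-brain barrier genes, 0 passed singly in limma, with 11 lower and 1 higher at an unadjusted p under 0.05 (2 fell and 1 rose when adjusted over the list alone). The list fell (median -0.06, mean -0.22, adjusted p = 0.000246, and adjusted p = 0.607 with an estimated correlation). The 21 members that rose in DAPI-positive ECs had a median of -0.34 in the mutants, and 15 of them lay below 0 on both arrays. Ribosomal protein genes also fell (0 of 85 singly, 7 lower at an unadjusted p under 0.05, 1 adjusted over the list alone; median -0.18, adjusted p = 1.69e-06, and adjusted p = 0.607 with an estimated correlation). Oxidative phosphorylation genes fell (0 of 96 singly, 4 lower at an unadjusted p under 0.05; median -0.08, adjusted p = 0.00529, and adjusted p = 0.62 with an estimated correlation), as did lymphocyte markers (0 of 12 singly, 1 lower unadjusted; median -0.13, adjusted p = 0.0375, and adjusted p = 0.607 with an estimated correlation). Without replicate 2 these lists had adjusted p of 0.161 and 0.183, and the lymphocyte list had 0.0702 without replicate 1 and 0.579 after median centring. With the software's processed signals the ribosomal and oxidative phosphorylation lists had 0.219 and 0.106.

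Other lists called in gpr124 mutants rested on replicate 2. Skeletal muscle markers rose as a list (0 of 44 singly, 3 higher at an unadjusted p under 0.05; adjusted p = 1.69e-06, and adjusted p = 0.62 with an estimated correlation), with medians of 0.02 and 2.97 on replicates 1 and 2. Without replicate 2 that list and the epidermis list (0 of 41 singly, 2 higher and 1 lower unadjusted; median 0.28, adjusted p = 0.0228, and adjusted p = 0.624 with an estimated correlation) pointed downward, with adjusted p of 0.829 and 0.503. After median centring the epidermis list had 0.843. Eye and lens markers (0 of 48 singly, 7 higher unadjusted; median 0.39, adjusted p = 0.00129, and adjusted p = 0.607 with an estimated correlation) had 0.589 without it. Neuron markers (0 of 47 singly, 5 higher and 1 lower unadjusted, 1 adjusted over the list alone; median 0.21, adjusted p = 0.0154, and adjusted p = 0.607 with an estimated correlation) had 0.503. Glia markers (0 of 35 singly, 2 higher unadjusted; median 0.28, adjusted p = 0.0195, and adjusted p = 0.607 with an estimated correlation) had 0.607. Venous, lymphatic and scavenger genes (0 of 22 singly, 3 higher unadjusted; median 0.21, adjusted p = 0.0477, and adjusted p = 0.607 with an estimated correlation) had 0.607 and turned downward after median centring. Cell cycle genes fell as a list (0 of 75 singly, 3 lower unadjusted; median -0.15, adjusted p = 1.69e-06, and adjusted p = 0.607 with an estimated correlation), with medians of 0.01 and -0.31 on replicates 1 and 2, and had 0.589 without replicate 2.

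Leaving out either gpr124 replicate left 0 genes past the threshold in limma, with 1891 and 750 at an unadjusted p under 0.05 without replicates 1 and 2, against 2192 with both. The split was 136 higher and 139 lower after median centring, 82 and 5055 with no normalization, and 1 and 6 with the software's processed signals. With the 6 larval arrays alone 516 genes were higher and 64 lower, and with the 4 arrays of the slide 96 and 11. Within the slide slc16a1a, zic2b, zic2a and plvapa passed (adjusted p = 0.047 for each), while slc2a1a (0.0517) and slco2a1 (0.111) did not. The replicate difference of the wild-type EC channel in this comparison tracked that of the total EC channel across genes (r = 0.93), while the non-EC and mutant channels did not track each other (r = 0.12). Both comparisons thus carried the same replicate deviation, and their spreads are not independent.

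**Figure D3:**
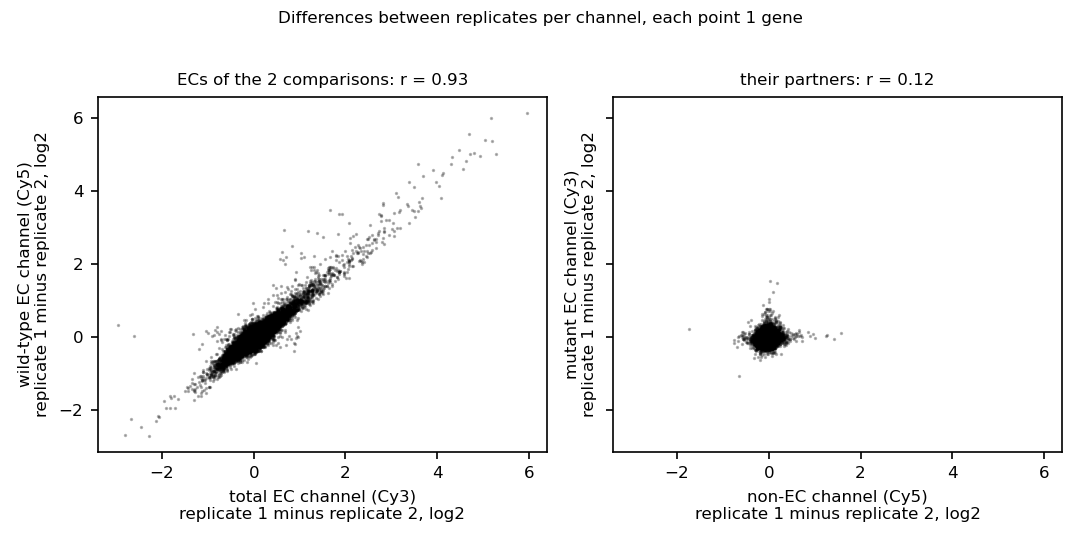
Replicate 1 minus replicate 2 on the log2 scale for each gene, with the total EC channel (x axis) against the wild-type EC channel of the gpr124 comparison (y axis) on the left and the non-EC channel (x axis) against the mutant channel (y axis) on the right; each point is 1 gene. The left points follow a line (r = 0.93) and the right points do not (r = 0.12).

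Across comparisons, genes higher in DAPI-positive ECs were mostly not those of the endothelium at large. All calls came from 1 fit with a spread per gene shared by the comparisons, and genes are not independent replicates. Fisher's test assumes independent genes and lists, so its p-values for the overlaps below only describe the lists. Of the genes higher in DAPI-positive ECs, 1371 were lower in total ECs, against 650.3 for independent lists (adjusted p = 1.29e-234), and 407 were higher there, against 366.7 (adjusted p = 0.0436). Of the genes lower in DAPI-positive ECs, 736 were higher in total ECs (276.0 for independent lists, adjusted p = 6.96e-166) and 183 lower (489.5 for independent lists). Of the 21 barrier genes that rose in DAPI-positive ECs, 6 rose, 7 fell and 8 did not pass in total ECs. Without DAPI replicate 2 these overlaps of 1371, 407 and 736 were 245, 71 and 175, the lowest with any 1 array left out, and their highest were 847, 197 and 361. Adult brain and DAPI-positive ECs shared 130 higher genes, against 79.5 (adjusted p = 5.74e-08), and lef1, slc2a1a and tnfrsf9a were among them. That overlap was 37 and 22 without DAPI replicates 1 and 2, and 966 and 811 without adult replicates 1 and 2. All 18 genes higher in gpr124 mutants were lower in total ECs, against 4.74 (adjusted p = 2.16e-10). That overlap was lost when any 1 array of either comparison was left out. Without a gpr124 array no gpr124 gene was called, so the loss was then fixed in advance. The other overlaps with 1 array left out also moved with the number of genes called. The log2 ratios correlated across genes, which are not independent replicates, at r = -0.437 (rho = -0.334) between DAPI and total ECs, 0.305 (rho = 0.292) between DAPI and gpr124, -0.304 (rho = -0.180) between total ECs and gpr124, 0.123 (rho = 0.0855) between adult and DAPI, -0.083 (rho = -0.0607) between adult and total ECs, and 0.0566 (rho = 0.057) between adult and gpr124. Single arrays of DAPI and total ECs correlated at -0.42, -0.49, -0.34 and -0.42, and replicate 2 of total ECs and of gpr124 at -0.47; the labels state the dyes and the populations compared differ, so the directions were kept.

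The correlation of total ECs with gpr124 carries the shared deviation of the EC channels. In 50 simulated draws with no effect, the sharing was set to the observed one. Their correlation of -0.908 and covariance of -0.0406 follow from that input, and the observed covariance was -0.108. The 0.06 genes called per comparison in these draws were too few for a simulated overlap. Between arrays of different replicate number the observed correlations were -0.239 and -0.0464, and between arrays of the same number -0.0535 and -0.475. The stronger value of each pair involves replicate 2 of gpr124, so these values cannot separate a shared control from that array. Part of the relation, and of the overlap of 18, may come from the shared control. The adult and DAPI ratios differed by a test of the difference for 3212 genes (1420 higher and 1792 lower in the adult ratio), and the gpr124 and total EC ratios for 7041 (4750 higher and 2291 lower in the gpr124 ratio). Without adult replicate 1 the first count was 8398, and without DAPI replicate 2 it was 821. Without replicate 2 of gpr124 the correlation of DAPI with gpr124 was 0.0541 and that of total ECs with gpr124 -0.0506.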

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

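The tests of an equally raised share of other cells, of the barrier genes that also rose in total ECs, of a dye effect, of dim signal and of bright probes were chosen after the results were seen.

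The adult ratio (brain over liver) and the larval ratio (DAPI-positive over DAPI-negative) of 9 marker genes differed by limma's test of the difference, with Benjamini-Hochberg adjustment, although the partners differ, being liver ECs in adults and DAPI-negative ECs in larvae. For 5 of them a channel on one side of the difference was not above background, so their difference has no measured size. Each value is the adult minus the larval log2 ratio with its standard error. The glucose transporter slc2a1a rose in both, by 7.29 in adults and at least 8.56-fold in larvae, where DAPI-negative ECs were not above background. Its fitted difference of 3.86 ± 0.69 (adjusted p = 0.0259) uses a fitted larval ratio of 3.43, of which only that bound was measured, so which ratio was larger is not settled. The tight junction gene cldn5b went opposite ways without passing in either, at -1.24 in adults and 1.04 in larvae, a difference of -2.27 ± 0.38 (adjusted p = 0.0224). Its relative cldn5a stood at 1.55 in larvae without passing (adjusted p = 0.0675). In adults it was not above background in brain ECs and above it in liver ECs on 1 array, with ratios of -0.15 and -2.07, so the fitted difference of -2.66 ± 0.62 (adjusted p = 0.0495) uses a fitted adult ratio whose size was not measured. The permeability gene plvapa fell by 0.58 in adults and stood at 0.23 in larvae, a difference of -0.81 ± 0.13 (adjusted p = 0.0218), while its other probe gave -0.02 and -0.22. The scavenger receptor stab1 stood at 0.53 in adults and -0.94 in larvae, a difference of 1.47 ± 0.16 (adjusted p = 0.00692), with its other probes between -1.33 and 0.18 in adults and between -0.68 and 0.93 in larvae. The hepatocyte gene fabp10a stood at -7.45 and 0.92, a difference of -8.37 ± 0.49 (adjusted p = 0.00143). For abcb4 (-2.27 ± 0.14, adjusted p = 0.00155), gfap (-2.28 ± 0.21, adjusted p = 0.00453) and apoa1a (-0.65 ± 0.14, adjusted p = 0.0385) no level was measured on the adult arrays, where neither channel was above background, so these differences rest on the larval ratios alone.

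Neurons, glia, muscle and epidermis had marker medians of 0.66, 0.82, 1.21 and 1.12 in DAPI-positive ECs, next to the barrier genes. A lower share of ECs that raises all other cell types alike is argued against by cartilage and fibroblast markers, with a median of -0.061 (array SD 0.18). That value cannot decide about a lower share in which only some other cell types are raised. A dye effect common to all arrays is argued against for the barrier genes that rose, whose median was 2.37 here and -0.34 in gpr124 mutants with the same dyes. For the 4 marker lists a dye effect cannot be told apart from other causes: their medians in gpr124 mutants were 0.21, 0.28, 1.57 and 0.28, all called higher, but at most 0.07 on replicate 1, and the wild-type partner differed between replicates. Non-endothelial RNA with the make-up of the non-EC sort is not the cause for every barrier gene, since 6 of the 21 also rose in total ECs over non-ECs on both arrays. RNA of a particular other cell type stays open, as neutrophil and lymphocyte lists rose there too. Both of these lists fell in DAPI-positive ECs, however, with medians of -0.9995 and -0.5991, so they name no source for the barrier genes. For the list as a whole, the 21 genes had a median of 0.15 in total ECs (array SD 0.077). By the bound set beforehand this would have argued against non-endothelial RNA. That bound was set aside after the values were seen, since 6 of the genes rose and 7 fell, and non-endothelial RNA stays open. Neural cells attached to brain vessels or a change in the ECs themselves, neither tested, may account for part of the pattern.

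The difference between the 2 total EC arrays mirrored that between the 2 gpr124 arrays (r = -0.91 across genes). An effect of single arrays that moves both channels is argued against by the non-EC and mutant channels, whose replicate differences correlated at 0.12, and more non-endothelial RNA in the mutant ECs of replicate 2 is argued against by the muscle markers, whose median differed by -0.14 between the mutant channels. The wild-type channel of the gpr124 arrays and the total EC channel correlated at 0.93 in their replicate differences, with muscle markers higher in replicate 1 by 2.62 and 2.57, so a candidate explanation is that each number stands for 1 wild-type EC sample placed on both arrays. The muscle, epidermis and eye lists that rose in gpr124 mutants by replicate 2 may then come from the wild-type partner. The labels do not say whether the RNA was shared, and no biological explanation was tested.

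The 2 adult arrays differed far more than the larval arrays, with a replicate correlation of 0.209 against 0.880 for DAPI, on the same slide. Signal below background as the whole cause is argued against by the 4525 genes well above it in both channels on both adult arrays. These correlated at 0.316, against 0.896 for such genes on the DAPI arrays. Brightness above background was not matched, as the median Cy3 signals were 37.2 and 39.7 on the adult arrays and 259 and 182 on the DAPI arrays. A dimmer signal thus stays open as a cause. Noise of single spots as the whole cause is argued against by 1534 genes with 2 bright probes, whose replicate differences correlated at 0.349. Over all 9476 genes with several probes that correlation was 0.176, between the bounds set for each, so a part for spot noise cannot be told apart there from transcripts lost or amplified unevenly or different cells collected. A difference between the adult fish or sorts stays open and was not tested.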

How the results depend on the processing

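The 6 larval arrays alone, the filter on the same channel of both adult arrays and the crossed block were chosen after the results were seen. With 2 arrays per comparison, calls depended on the other arrays that supplied the spread. Of the named genes that passed, 85 of 103 in total ECs, 30 of 95 in DAPI, 0 of 45 in adults and 0 of 6 in gpr124 stayed past the threshold under every alternative that tested them. Signal over background limits the adult comparison, with 19.2 and 25.7% of probes above background in Cy3, 27.9 and 35% in Cy5, and 10455 genes dim in both channels. The consensus correlation within a slide was 0 because each comparison lies in 1 slide, so a random slide block gives no value of its own; the ratios and list shifts within a slide are those given. For each count or value below that moved or changed sign the cause was not tested, except where fewer arrays, more probes tested or a stricter threshold account for it by construction. The correlation of DAPI with total ECs (-0.437) ran from -0.466 to -0.388 over its alternatives.

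Against the counts of 1536 genes in adults, 4331 in DAPI, 9169 in total ECs and 20 in gpr124, no background correction gave 114 in gpr124. The genes higher in DAPI and lower in total ECs then numbered 845 and those lower in total ECs and higher in gpr124 numbered 99. An offset of 16 gave 2448 in DAPI and 0 in gpr124 by limma (1894 at an unadjusted p under 0.05). The software's processed signals gave 2760 in adults, 1499 in DAPI and 7 in gpr124, with correlations of -0.0686 for adult with total ECs and 0.0423 for adult with gpr124. Overlaps were then 63 genes higher in adults and DAPI, 469 higher in DAPI and lower in total ECs, 406 lower in DAPI and higher in total ECs, 126 higher in both of these and 1 lower in total ECs and higher in gpr124. The deposited series matrix gave 2764, 1500 and 7.

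Median centring gave 2343 in adults, 275 in gpr124 and 11 adult lists past the threshold. Correlations were 0.158 for adult with DAPI, -0.0958 for adult with total ECs, 0.193 for adult with gpr124 and 0.503 for DAPI with gpr124, and overlaps were 50 higher in adults and DAPI, 154 higher in DAPI and total ECs, and 119 lower in total ECs and higher in gpr124. In DAPI, klf6a turned to -0.16. As the signed normal score of the list test, the immediate early list in DAPI turned to -0.12 (adjusted p = 0.925, over alternatives 0.000142 to 0.925) and the venous list in gpr124 to -2.13 (adjusted p = 0.0642, over alternatives 0.00483 to 0.607). No normalization gave 2698 in adults, 10184 in DAPI and 5137 in gpr124. In DAPI the genes axin1 (-0.36), aqp8a.1 (-0.053), dla (-0.24), aqp1a.1 (-0.069), apoa1a (-0.10), acta1a (-0.51), crygm2a (-0.11), crygm2d2 (-0.16), dusp1 (-0.30), ier5l (-0.42) and klf6a (-0.73) then turned negative, with the median gene at -0.58.

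Probes bright in both channels gave a correlation of -0.0892 for adult with total ECs. Averaging all probes turned plvapa in total ECs to 1.62 and that correlation to -0.0738, and testing every probe gave 9114 calls in DAPI and 16258 in total ECs. An intensity trend gave 122 in gpr124, and array weights gave 710 in adults, 7141 in DAPI and 630 in gpr124. The 4 arrays of the same slide gave 299 in adults, 1279 in DAPI and 1.1e+02 in gpr124 (96 higher and 11 lower). The 2 arrays of a comparison alone gave 0 in adults (1154 at an unadjusted p under 0.05 in limma), 8944 in DAPI and 0 in gpr124 (3152 unadjusted). At least 2-fold change left 1371 in DAPI and 4295 in total ECs, and an adjusted p under 0.01 left 851, 1291, 5870 and 0 (2192 unadjusted in gpr124). The 6 larval arrays gave 8872 in DAPI and 580 in gpr124, and the same-channel filter gave 2051 in adults. With an estimated correlation camera called 0 lists in adults, 0 in DAPI, 1 in total ECs and 0 in gpr124, with 4, 5, 5 and 1 at an unadjusted p under 0.05. For 54 of the 58 called lists this gave the highest adjusted p of any alternative, and the lowest was at most 0.0105 for each. For the adult heat shock list the estimate was 0.011, near the preset 0.01, yet its unadjusted camera p went from 9.14e-11 to 0.00307. In DAPI the Wnt and fenestrated lists had estimates of 0.00547 and -0.0199, below the preset. Their unadjusted camera p still went from 0.00616 to 0.044 and from 0.00283 to 0.0328. A higher correlation thus does not account for every lost call, and a lost call alone does not show that members were correlated.

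Replicate numbers were checked for pairing: deviations of same-numbered arrays correlated at -0.907 between total ECs and gpr124 and at -0.0157 to 0.0044 between all other pairs, so the numbers do not pair the arrays of all comparisons. With that number as a block, 2395 genes passed in DAPI and 0 in gpr124 by limma (1591 unadjusted), and 1444 differed between adults and DAPI. Overlaps with the block were 64 higher in adults and DAPI, 710 higher in DAPI and lower in total ECs, 421 lower in DAPI and higher in total ECs, 220 higher in both of these and 0 lower in total ECs and higher in gpr124. A crossed block gave 9218 in total ECs and 160 in gpr124.

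Leaving out either replicate gave 5523 to 5876 genes in adults, 639 to 1160 in DAPI, 4906 to 5315 in total ECs and 0 in gpr124 (1891 without replicate 1 and 750 without replicate 2 at an unadjusted p under 0.05 in limma), the lone array being assumed to vary like the others. The gpr124 lists past the threshold numbered 3 to 11. The muscle list there ran from -0.31 without replicate 2 (adjusted p = 0.829, over alternatives 2.92e-16 to 0.829) to 8.59 without replicate 1 in signed normal score, and the epidermis list from -0.99 (adjusted p = 0.503, over alternatives 1.16e-06 to 0.843) to 5.27. Genes that differed between adults and DAPI numbered 821 to 8398, and between gpr124 and total ECs 3932 to 4683. Correlations ran from 0.0777 to 0.123 for adult with DAPI, -0.0835 to -0.0603 for adult with total ECs, 0.0307 to 0.0578 for adult with gpr124, 0.0541 to 0.369 for DAPI with gpr124 and -0.384 to -0.0506 for total ECs with gpr124. Overlaps ran from 22 to 966 higher in adults and DAPI, 245 to 847 higher in DAPI and lower in total ECs, 175 to 361 lower in DAPI and higher in total ECs, and 71 to 197 higher in both of these, with 0 lower in total ECs and higher in gpr124.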

Other observations

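The genes singled out here were chosen after their values were seen, and no explanation was tested for them. A set of 24 genes rose in adult brain ECs, in DAPI-positive ECs and in total ECs, and 6 of them lay below 0 on both gpr124 arrays, while 0 of the 130 genes higher in adult brain and DAPI-positive ECs were called lower in the mutants by limma (11 at an unadjusted p under 0.05). Of all 22280 genes, 66.3% had the same sign on both gpr124 arrays, and 2192 had an unadjusted p under 0.05 there in either direction. The counts of 6 and 11 were not tested against all genes. The protease gene bmp1b rose by 6.70 ± 0.31 in adult brain ECs (adjusted p = 4.62e-05), 3.17 ± 0.12 in DAPI-positive ECs (adjusted p = 0.00144) and 1.19 ± 0.04 in total ECs (adjusted p = 0.00114). The receptor gene tnfrsf9a, a member of the tumour necrosis factor receptor family, rose by 2.92, 4.43 and 1.02 and stood at -1.44 in gpr124 mutants (adjusted p = 0.119). The RNA-binding protein gene rbpms2b rose by 5.49, 1.89 and 1.97, the oxysterol hydroxylase gene cyp7b1 by 4.02, 1.76 and 1.18, and lnx2b by 3.92, 0.91 and 1.32. The claudin cldn12 rose by 2.49, 0.71 and 0.76, the signalling gene smad9 by 1.45, 0.68 and 1.62, and the angiopoietin receptor tek by 1.69, 0.90 and 3.65. The LIM protein gene csrp2 was at least 7.03-fold higher in adult brain ECs and rose by 3.00 in DAPI-positive and 1.05 in total ECs, with -0.48 in the mutants (adjusted p = 0.602). For klf6a, also in the set, the DAPI ratio of 0.62 turned negative under other scalings.

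Of the 33 lists, 7 had no call in any comparison by camera with Benjamini-Hochberg adjustment. Solute carriers had 51 members higher and 15 lower of 329 in DAPI-positive ECs (51 and 17 adjusted over the list alone; median 0.11, adjusted p = 0.276), and 34 higher and 134 lower in total ECs (40 and 135 adjusted over the list alone; median -0.27, adjusted p = 0.0502). Glycolysis and hypoxia genes had 2 higher and 18 lower of 45 in total ECs (2 and 18 adjusted over the list alone; median -0.55, adjusted p = 0.137). Mural cell markers, genes of the pericytes and smooth muscle around vessels, had 3 higher and 2 lower of 22 in DAPI-positive ECs (7 and 2 adjusted over the list alone; median 0.41, adjusted p = 0.104), and 4 higher and 0 lower in adult brain ECs (4 adjusted over the list alone; adjusted p = 0.0989). Genes of p53 and apoptosis had 12 higher and 7 lower of 43 in total ECs (12 and 7 adjusted over the list alone; median 0.26, adjusted p = 0.0595). Matrix and basement membrane genes had 9 higher and 15 lower of 37 in total ECs (adjusted p = 0.432) and 5 of each in DAPI-positive ECs (adjusted p = 0.342). Macrophage and microglia markers had 6 higher and 6 lower of 35 in total ECs (adjusted p = 0.497) and 4 and 3 in DAPI-positive ECs (adjusted p = 0.725), and ABC transporters 4 and 8 of 36 (adjusted p = 0.497) and 4 and 5 (adjusted p = 0.725).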
